A study of Drosophila melanogaster with 120 samples.

How the data were processed

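Transcript levels were measured in heads and abdomens of unmated Drosophila melanogaster females on 120 NimbleGen arrays with a single dye, Cy3. Per the labels, selection populations had been bred for a longer reproductive lifespan by delaying mating to 28 and later 40 days of age, and control populations had been mated at 14 days. RNA was sampled after 35 generations at 25 °C. Each regime had 3 populations, sampled on days 1, 5, 15, 30 and 50 with 2 biological replicates, which gives 6 arrays in each of the 20 groups of tissue, regime and day. The title of the day-15 head of control population 3 used as biological replicate 1 gives replicate 3 instead.

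The deposited values are log2 intensities that the authors made with RMA, a method that corrects background, normalizes by quantiles and summarizes probes into 1 value per transcript. The RMA version, the arrays that were normalized together, the genome build and the annotation release are not given in the sources used here. All 16637 transcripts of the array, each identified by a FlyBase transcript number, were tested. Array medians lay between 9.93 and 10.44 in abdomens and between 9.45 and 10.03 in heads on the log2 scale. Arrays give no read depth, and their number limits the precision.

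Selection acted on whole populations, so the population was the replicate. The 2 biological replicates of a population and day were averaged. For the regime effect, each population was then averaged over the 5 days, and 3 selection populations were compared with 3 control populations. For effects of age, the 30 averages of a tissue were fitted with population, day and regime by day, leaving 16 residual degrees of freedom. Day 50 minus day 5 was called ageing and day 5 minus day 1 maturation, both averaged over the regimes, and a further contrast compared the ageing change of selection with that of control. Heads were compared with abdomens over the 12 averages of population and tissue, with population as a block and a difference of at least 2-fold required. Differences between tissues in the regime effect and in ageing were tested on the head minus abdomen differences of the populations. All these fits used limma 3.58.1 in R 4.3.3 with an intensity trend in the moderated variance, two-sided tests and Benjamini-Hochberg adjustment over the 16637 transcripts of each contrast, at an adjusted p of 0.05.

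An ageing index gave the size of the ageing change of each population. The 200 transcripts with the strongest rise and the 200 with the strongest fall from day 5 to day 50 were chosen on the populations of the other numbers. The index was the mean change of the rising transcripts minus that of the falling transcripts, compared between regimes by a two-sided exact permutation test whose smallest possible p is 0.1. A day-1 score placed each array between the median profile of days 5 to 50, set to 0, and the median profile of day 1, set to 1. It used 200 transcripts each way chosen on the other population numbers.

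These contrasts, their tests and the naming rule were fixed before the data were examined. The rule was to name, for each contrast, up to 12 genes each way with the largest change among those past the threshold that moved the same way in every population, plus 2 each way without a gene symbol. Where none passed, the 3 with the smallest p each way were to be given as values, of which only some are given here. The plan to test 1 transcript per gene could not be followed, because no table joining transcript numbers to genes was used here, and each transcript was tested by itself, as the plan's alternative foresaw. Synonyms in the RefSeq gene table (assembly Release 6 plus ISO1 MT) tied 16 transcripts to a single gene, 8 of them through a whole synonym and 8 through part of a composite synonym. A further 28 transcripts matched several genes and were left unnamed, as were the other 16593. The 42 gene lists written in advance each held at most 1 named transcript, under the minimum of 3, so no list was tested, and no coordinates are given.

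Each fit was tested on simulated arrays with the means and spreads of the real ones. Of the transcripts changed 2-fold there, 98% were recovered for the regime effect in abdomens and 92% in heads, 94% and 90% for ageing, 84% and 92% for maturation, and 36% and 50% for the regime difference in ageing. Recovery was 74% for the tissue difference in the regime effect and 68% for the tissue difference in ageing. It was 48% for the tissue effect, whose 2-fold limit lies at the size put in. In these simulations transcripts varied independently, and 50 were changed at each size up to 4-fold in every contrast. Shared variation among real populations, or fewer real changes, may make recovery lower than these percentages. FBtr0071304, with a 2.02-fold regime difference in abdomens, did not pass. Alternatives planned in advance were quantile normalization or median centring of the arrays, only transcripts with a mean signal above the median, no intensity trend, a single biological replicate, each population left out, population number as a block, no block, all arrays with population as a random block, no day 1, a linear slope on day and an F test over all days. After the data had been seen, further alternatives left out arrays whose day-1 score contradicted their day or whose correlations were low, and the thresholds of these exclusions were set with the scores in view. No array was left out of the main comparisons.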

Results

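The data were 120 transcript profiles of unmated female flies, 60 of abdomens and 60 of heads. Selection for a longer reproductive lifespan and its control each had 3 populations, sampled at 5 ages. Values ran from 7.03 to 15.83 on the log2 scale in abdomens and from 7.01 to 15.76 in heads. The median correlation across transcripts between the 2 biological replicates of a population and day was 0.987 in abdomens and 0.982 in heads. Day accounted for 55% of the sum of squares in abdomens and 23.6% in heads, with 4 degrees of freedom. Regime accounted for 0.942% and 3.6% with 1 degree of freedom, and populations within regimes for 6.77% and 8.2% with 4. Biological replicates accounted for 18.3% and 34.4% with 30.

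The youngest flies had a distinct profile in both tissues. On the day-1 score, 10 of the 12 abdomens of day 1 lay between 0.95 and 1.05, and the 48 abdomens of later days between -0.0509 and 0.219. Among heads, 8 of the 12 of day 1 lay between 0.929 and 1.4, and 45 of the 48 of later days between -0.0886 and 0.198. The 5 heads on the side opposite to their label were both day-1 heads of control population 3 (-0.0504 and -0.0437), its day-30 head of replicate 1 (0.941), the day-30 head of selection population 3, replicate 2 (1.05), and the day-50 head of control population 2, replicate 1 (1.23). Both abdomens (0.542 and 0.536) and both heads (0.468 and 0.455) of control population 1 on day 1 lay in between. These arrays were kept, so head contrasts of days and head averages over days include profiles out of place for their age.

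**Figure D1:**
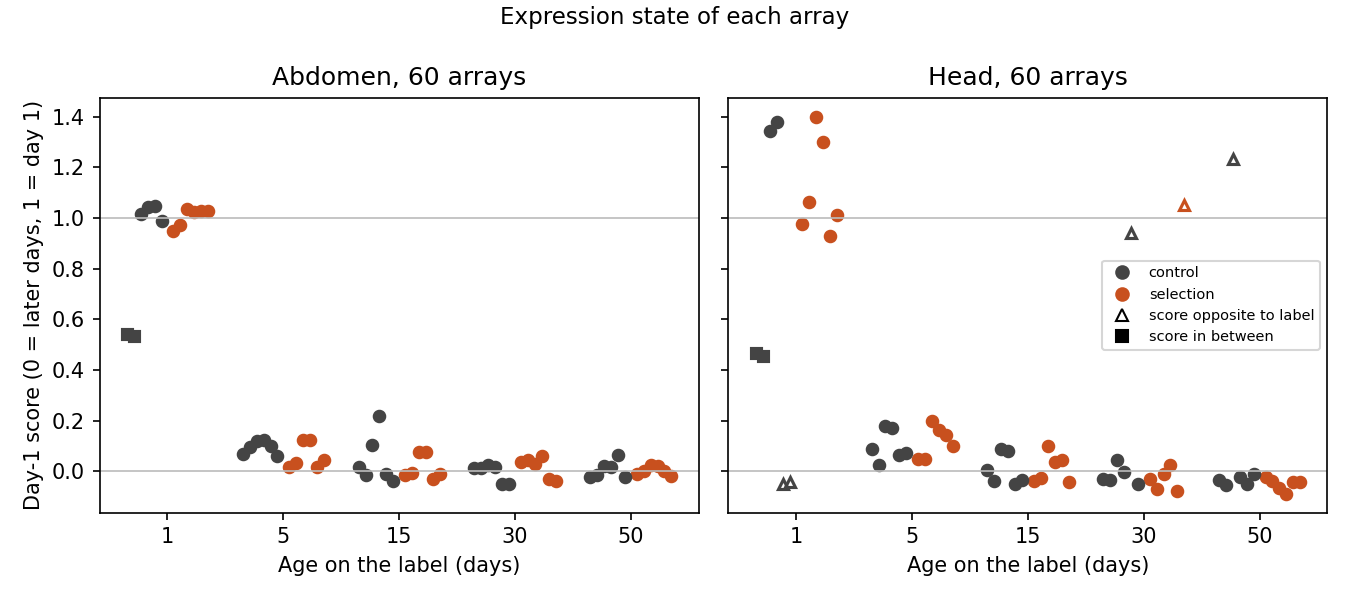
Day-1 score (no unit) of each of the 60 abdomen and 60 head arrays by age in days, with 1 point per array, control in grey and selection in orange. Triangles mark the 5 heads whose score was opposite to their label, and squares mark the 4 arrays of control population 1 on day 1 that lay in between.

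Heads and abdomens differed in 5597 of the 16637 transcripts by at least 2-fold, 1731 of them higher in head and 3866 lower in head. FBtr0083857 was 7.23 higher in head on the log2 scale, at 15.45 ± 0.0314 against 8.23 ± 0.0789 in abdomen (SD, n = 6 populations). FBtr0081030 was 6.79 higher in head. FBtr0077040 and FBtr0077041 were lower in head, with log2 differences of -7.17 and -7.16. In heads these transcripts stood near the highest (15.76) or lowest (7.01) values measured, where arrays resolve levels poorly, so the sizes are approximate. All 6 genes with a symbol that passed were lower in head: sle (-2.77), rdx (-1.76), SuUR (-1.40), Wdr24 (-1.36), Uba1 (-1.01) and kis (-1.0). The transcripts of sle stood at 10.81 ± 0.156 in head and 13.59 ± 0.0985 in abdomen (SD, n = 6), with a limma adjusted p of 2.45e-13. Of the 5597 transcripts, 5596 differed in the same direction in all 6 populations. The split between higher and lower rests on the scaling, because the median transcript differed by -0.25 as deposited, by -0.03 after quantile normalization over all arrays (2430 higher, 2180 lower) and by 0.18 after median centring (2592 higher, 2284 lower). After quantile normalization and median centring, sle (-2.29 and -2.34) and rdx (-1.42 and -1.32) still differed by at least 2-fold, while SuUR (-0.78 and -0.96), Wdr24 (-0.78 and -0.93), Uba1 (-0.59 and -0.57) and kis (-0.36 and -0.57) stayed lower in head but not by 2-fold. Leaving out control population 1 also took Uba1 (-0.96) and kis (-0.90) under 2-fold, as did leaving out selection population 1 for Uba1 (-0.99) and control population 3 for kis (-0.92).

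Abdomens changed widely between day 1 and day 5, the interval called maturation here. Of the 16637 transcripts, 4410 rose and 3952 fell, 3173 of them by at least 2-fold. FBtr0079808 fell by 6.30 on the log2 scale, from 14.68 ± 0.361 to 8.39 ± 0.237 (SD, n = 6), and FBtr0070504 fell by 5.96. FBtr0076196 rose by 5.10 and FBtr0077013 by 4.21. Among the 16 transcripts with a gene symbol, 9 rose and 3 fell. The rises were 1.64 for fend, 0.93 for sle, 0.92 for NaPi-III, 0.90 for rdx, 0.77 for SuUR, 0.76 for Wdr24 and 0.35 for HDAC3 in all 6 populations, and 1.05 for kis and 0.24 for His4r in 5 of 6. Fatp1 (-1.36), LanA (-0.996) and alpha-Spec (-0.47) fell in all 6 populations. The call of alpha-Spec ended without control population 2 (-0.38), without selection population 1 (-0.41) and without selection population 3 (-0.45). The transcript of fend went from 10.00 ± 0.316 to 11.64 ± 0.262 (SD, n = 6; limma adjusted p 2.20e-08). In control population 1, whose day-1 abdomens were intermediate, FBtr0076196 rose by only 0.12, FBtr0077013 by 1.65 and FBtr0070504 changed by -4.03.

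Heads changed in fewer transcripts over the same days, 1630 rising and 1619 falling. FBtr0074364 rose by 4.44 and FBtr0076387 by 3.94, while FBtr0082826 (-3.62) and FBtr0087917 (-3.57) fell. Of the genes with a symbol, His4r rose by 0.47, from 14.37 ± 0.238 to 14.83 ± 0.110, and LanA fell by 0.52 on the log2 scale (SD, n = 6; limma adjusted p 0.0032 and 0.0335). The call of LanA ended without control population 1 (-0.48), control population 2 (-0.53), selection population 1 (-0.51) or selection population 2 (-0.46). Both tissues shared 1557 transcripts that changed in the same direction, against 817 expected by chance, and 563 that changed in opposite directions, against 816. Across transcripts, which are not independent replicates, the maturation changes of the tissues had a Pearson correlation of 0.331 and a Spearman correlation of 0.21. The head count was 2094 without control population 1, 1781 without control population 2, 1612 without selection population 1 and 1905 without selection population 2. It was 560 with biological replicate 1 alone, and 2 of the 32 ways of exchanging days 1 and 5 within populations gave as many transcripts, the real one and another with 3349. It was 5300 (2739 up, 2561 down) without the arrays of opposite score or low correlation, and 1698 of the 3249 moved alike in all 6 populations.

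Ageing from day 5 to day 50 changed few transcripts in abdomens. Of the 16637, 75 rose and 77 fell, 60 of them by at least 2-fold. FBtr0087436 rose by 2.69 on the log2 scale, from 9.14 ± 0.0818 to 11.83 ± 1.36 (SD, n = 6), and FBtr0076571 rose by 2.40. The call of FBtr0087436 ended without control population 2 (2.42) or selection population 3 (2.27), and that of FBtr0076571 without control population 3 (2.08) or selection population 1 (2.39), 2 (2.13) or 3 (2.68). FBtr0290272 fell by 2.18 and FBtr0086819 by 2.12 on the log2 scale, the latter from 10.94 ± 0.273 to 8.82 ± 0.311 (SD, n = 6; limma adjusted p 5.37e-06). In 139 of the 152 transcripts the direction was the same in all 6 populations. FBtr0290272 had already fallen from 14.09 on day 1 and reached 8.95 by day 15. FBtr0086819 stood at 10.25 on day 1, under its day-5 level. With maturation taken from biological replicate 1 and ageing from replicate 2, 20 transcripts fell in both, against 5.59 expected by chance. With the replicates exchanged, 26 did, against 6.68. Rises in both numbered 2 against 1.85, and 1 against 8.24. Part of the fall counted as ageing in abdomens thus continued the earlier fall. No gene with a symbol passed, and LanA had the smallest p among them, with a log2 change of -0.27. Between days 5 and 15, 20 transcripts rose and 102 fell in abdomens (17 and 60 without arrays of low correlation), and none passed in limma between days 15 and 30 (263 at an unadjusted p under 0.05) or between days 30 and 50 (873). The ageing count was 98 without control population 2, 88 without control population 3, 75 without selection population 1, 75 without selection population 2 and 45 without selection population 3. With biological replicate 1 or 2 alone it was 74 or 34.

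In heads, 178 transcripts rose and 115 fell from day 5 to day 50, 91 of them by at least 2-fold. FBtr0077086 rose by 2.76 and FBtr0091895 by 2.72, the latter from 8.52 ± 0.240 to 11.24 ± 0.455 (SD, n = 6; limma adjusted p 7.63e-05). FBtr0078265 fell by 2.84 on the log2 scale, from 13.90 ± 0.426 to 11.06 ± 0.736 (SD, n = 6), and FBtr0080558 fell by 2.66. FBtr0078265 stood at 14.3 on day 1 and had reached 11.72 by day 15, so most of its fall came early. The call of FBtr0080558 ended without control population 1 (-2.51) or selection population 1 (-2.71), 2 (-2.59) or 3 (-2.67). The direction was the same in all 6 populations for 277 of the 293 transcripts. No gene with a symbol passed, and the smallest p values were those of Wdr24 (log2 change 0.20) and His4r (log2 change -0.14). Over single intervals, 1 transcript was lower on day 15 than on day 5, 0 differed between days 15 and 30 (limma; 1144 at an unadjusted p under 0.05) and 1 was higher on day 50 than on day 30. Without the arrays of opposite score or low correlation these intervals gave 25 up and 50 down, 22 up and 3 down, and 27 up and 6 down. The ageing count in heads was 166 without control population 1, 103 without selection population 1, 118 without selection population 2 and 125 without selection population 3. With biological replicate 1 or 2 alone it was 55 or 180. Without the 5 heads of opposite score it was 835 (433 up, 402 down), and without arrays of low correlation as well it was 1353 (637 up, 716 down).

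**Figure D2:**
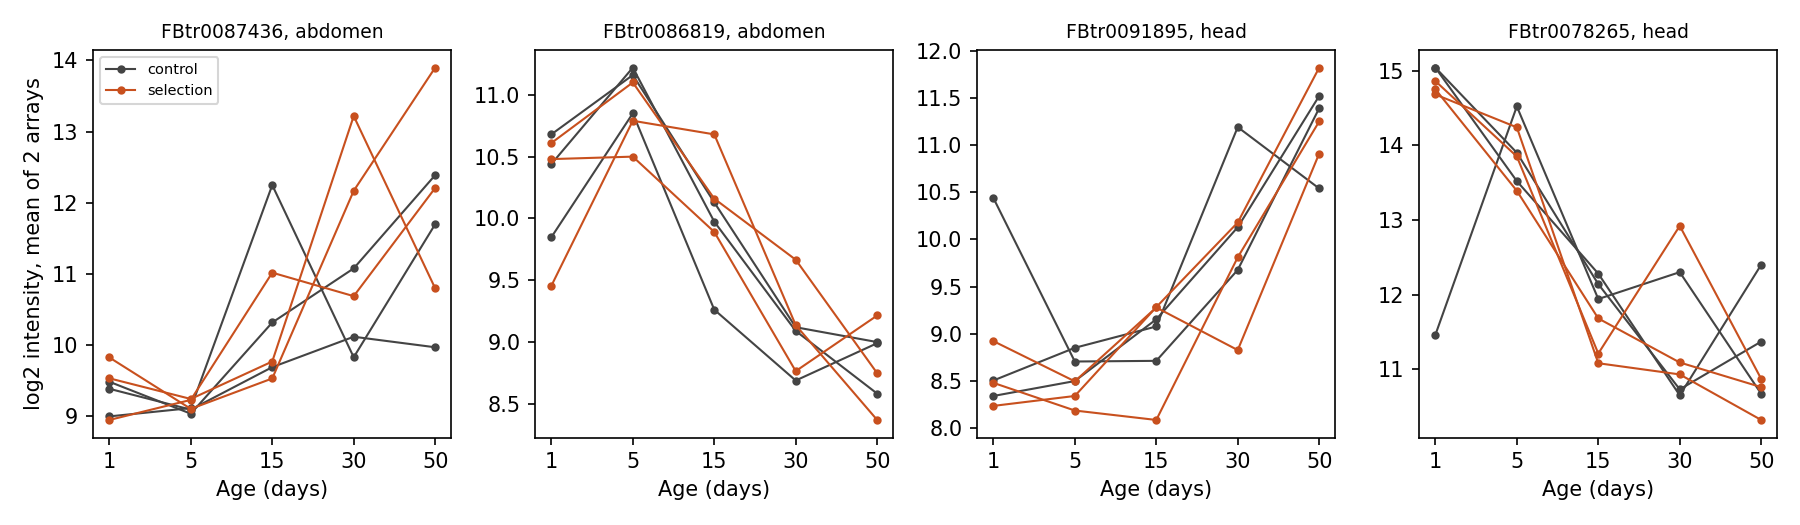
Log2 intensity against age in days for FBtr0087436 and FBtr0086819 in abdomens and FBtr0091895 and FBtr0078265 in heads, with a line for each population, control in grey and selection in orange, and each point the mean of 2 arrays. FBtr0087436 and FBtr0091895 lie higher on day 50 than on day 5 in every population, and FBtr0086819 and FBtr0078265 lie lower.

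The tissues shared part of the ageing change. Of the transcripts past the threshold, 15 rose and 9 fell in both tissues, 24 against 1.33 expected by chance, and 0 moved in opposite directions, against 1.34. Without the arrays of opposite score or low correlation, 26 rose and 31 fell in both, against 7.61 expected in the same direction, and 3 moved in opposite directions, against 7.6. Across all transcripts the relation was weak, with a Pearson correlation of 0.238 and a Spearman correlation of 0.144 between the ageing changes of abdomen and head (0.213 and 0.0721 without the arrays of opposite score or low correlation). The change differed between tissues for 203 transcripts, 103 with the higher change in head and 100 with the lower. FBtr0082621 changed by 2.69 ± 0.727 in head and 0.05 ± 0.147 in abdomen, and FBtr0091895 by 2.72 ± 0.623 and 0.19 ± 0.522 (SD, n = 6). FBtr0078265 differed by -2.56 and FBtr0080558 by -2.49 between head and abdomen. On day 5 in abdomens FBtr0082621 (7.82) and FBtr0080558 (8.59) stood near the lowest values measured and FBtr0091895 (14.16) nearer the highest. There arrays resolve changes poorly, so for these transcripts the tissues may differ in level rather than in ageing. FBtr0078265 (10.56) stood between. In 186 of the 203 the difference had the same direction in all 6 populations. The count was 128 without control population 1, 109 without selection population 2 and 114 without selection population 3, and 346 without the 5 heads of opposite score. It was 6 with biological replicate 1 alone.

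**Figure D3:**
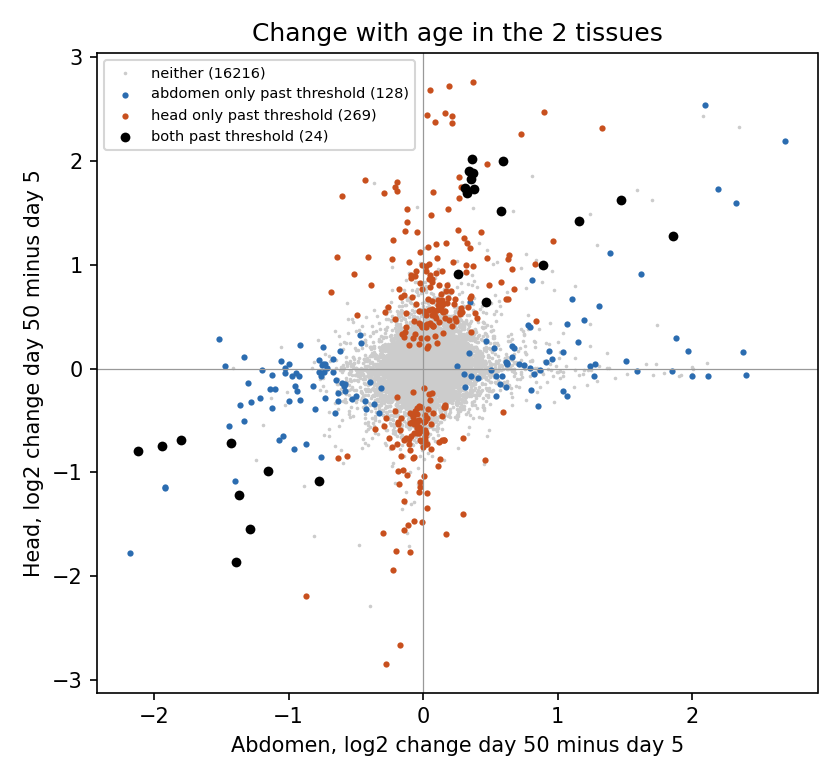
Log2 change from day 5 to day 50 in head against that in abdomen, with 1 point for each of the 16637 transcripts. Black points are the 24 past the threshold in both tissues, all of which moved in the same direction in each.

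Selection for a longer reproductive lifespan moved no transcript past the threshold in either tissue. In abdomens, limma gave 0 transcripts and 225 at an unadjusted p under 0.05, where chance would give 832. In heads it gave 0, with 2755 at an unadjusted p under 0.05, 1480 of them higher in selection, and a smallest adjusted p of 0.231. FBtr0086238 was 0.62 higher in selection heads, at 11.43 ± 0.109 against 10.81 ± 0.0493 (SD, n = 3), and FBtr0076331 was 0.63 higher. FBtr0080691 (-0.64) and FBtr0081161 (-0.49) were lower in selection heads. The transcript of kis was 0.44 higher, at 11.32 ± 0.144 against 10.88 ± 0.162 (SD, n = 3), with a limma adjusted p of 0.231. In abdomens the smallest p values among transcripts higher in selection were those of FBtr0100095 (log2 difference 0.91) and FBtr0083971 (log2 difference 0.79). Among those lower, FBtr0071304 (log2 difference -1.02) had the smallest p, and all 3 had an adjusted p of 0.9999 in limma. The count at an unadjusted p under 0.05 in abdomens was 356 without control population 1, 546 without control population 2 and 136 without selection population 1, and in heads it was 1567 without control population 1 and 1616 without selection population 2. With biological replicate 1 alone it was 143 in abdomens and 683 in heads. Without selection population 1, 1 transcript passed in heads. With all arrays and population as a random block, 47 transcripts passed in heads and 0 in abdomens. The correlation within populations was estimated at 0.0245 in heads, so arrays counted almost as independent replicates of the regime. With population number and biological replicate as a further block, 2379 passed in heads and 1 in abdomens, but that fit put the correlation within populations at -0.0137 in heads and so counted arrays as if they were independent.

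The regime effects of the tissues resembled each other across transcripts, with a Pearson and a Spearman correlation of 0.388 between abdomen and head. The highest value among the other 9 splits of the 6 populations was 0.351, and 10 splits are too few for a share under 0.05. A difference between tissues in the regime effect was found for 0 transcripts in limma, with 556 at an unadjusted p under 0.05. That number was 237 without control population 1, 1639 without control population 2, 322 without selection population 2 and 214 with biological replicate 1 alone. Of the transcripts with the smallest p there, FBtr0086238 had the larger head excess in selection (0.65) and FBtr0100095 the smaller (-0.93). With all arrays and population as a random block, 5 transcripts passed. The correlation within populations over both tissues was estimated at 0.0384, so arrays again counted almost as independent.

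The ageing change did not differ detectably between regimes. In abdomens limma gave 0 transcripts, with 840 at an unadjusted p under 0.05, and an F test over all days gave 1 past the threshold. In heads it gave 0, with 157 at an unadjusted p under 0.05. The abdominal number was 1614 without control population 2, 497 without control population 3, 144 without selection population 1, 1586 without selection population 2 and 398 without selection population 3. The head number was 331, 403 and 242 without control population 1, 2 or 3. These numbers were 1731 and 341 with biological replicate 1 alone. In heads the F test over all days gave 0 past the threshold. It gave 940 at an unadjusted p under 0.05, where chance would give 832. That test includes day 1, on which some control heads scored out of place. The contrast gave 546 at an unadjusted p under 0.05 without the arrays of opposite score or low correlation. FBtr0086889 had the smallest p in abdomens, changing by 0.76 ± 0.511 in selection and -0.59 ± 0.147 in control (SD, n = 3), and LanA changed by 0.05 and -0.58. In heads FBtr0082738 changed by -0.79 ± 0.183 in selection and -0.13 ± 0.169 in control (SD, n = 3). Within regimes, the ageing changes of control and selection had a Pearson correlation across transcripts of 0.31 in abdomens and 0.538 in heads, and a Spearman correlation of 0.0335 and 0.345, so that by rank the abdominal changes were almost unrelated. Between them they shared 11 abdominal and 20 head transcripts past the threshold, with 0 in opposite directions, against 0.0255 and 0.0702 expected in the same direction. Both regimes' changes came from the same fit, with 1 residual variance for each transcript. This can raise the overlap, so the expected numbers for the regimes may be too low. Without the arrays of opposite score or low correlation, the regimes shared 206 head transcripts (114 up, 92 down) against 5.46 expected, with 0 in opposite directions, a Pearson correlation of 0.661 and a Spearman correlation of 0.486, and 15 in abdomens. On simulated arrays this contrast recovered 36% and 50% of 2-fold differences, so smaller differences would mostly go undetected.

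The ageing index asked whether selection populations changed less with age. In abdomens it was 1.01 ± 0.179 in selection and 1.25 ± 0.140 in control (SD, n = 3), a difference of -0.24 with an exact permutation p of 0.2. It was -0.10, -0.12 and -0.15 without control population 1, 2 or 3, -0.16 without selection population 2 and -0.38 without selection population 3. Without arrays of low correlation it was -0.25, with an exact permutation p of 0.1, the smallest the design allows. In heads it was 1.54 ± 0.0127 in selection and 1.21 ± 0.277 in control (SD, n = 3), a difference of 0.33 with an exact permutation p of 0.1, the smallest the design allows. The head difference rested on control population 2, whose index was 0.89 and whose day-50 head of replicate 1 had a day-1 score of 1.23. Without that population it was 0.05. Without the 5 heads of opposite score it was 0.00711, and without arrays of low correlation as well it was -0.05.

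**Figure D4:**
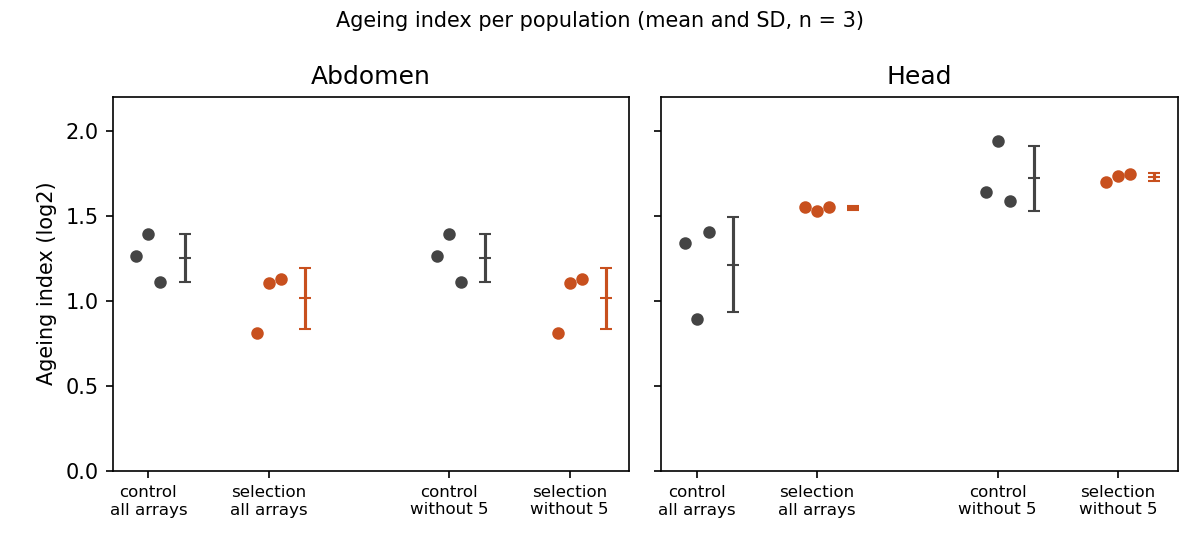
Ageing index (mean log2 change of rising minus falling transcripts) of each population in abdomens and heads, with the mean and SD of 3 populations, for all arrays and without the 5 heads of opposite score. In heads the control populations lay at 1.34, 0.89 and 1.40 with all arrays, under the selection populations at 1.55, 1.53 and 1.55.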

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

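Among the tests below, those of poor hybridisation, of the state of the flies and of a single faulty array were chosen after the result had been seen, as were the limits that define arrays of opposite, intermediate or low-correlation profile and the spread required in the test of exchanged arrays.

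In 16 of 82 groups of 6 values a single value stood apart from the rest, where chance flags about 1 in 20 groups, or 4.1. On the day-1 score, the outlying heads were those of control population 2 on day 50, replicate 1 (1.23, nearest -0.0121), of selection population 3 on day 30, replicate 2 (1.05, nearest 0.0251) and of control population 3 on day 30, replicate 1 (0.941, nearest 0.0439). On the median correlation with its tissue, the outlying abdomens were those of control population 3 on day 50, replicate 1 (0.945), and control population 2 on day 15, replicate 2 (0.796). The outlying heads were those of control population 2 on day 15, replicate 2 (0.900), of selection population 3, replicate 1, on day 1 (0.872), day 5 (0.958) and day 15 (0.916), of the same population on day 30, replicate 2 (0.921), and of control population 3 on day 30, replicate 1 (0.863). Of the 42 transcript changes named in the contrasts, 5 had a population apart. FBtr0080558 changed by -0.323 with age in heads of control population 2 (nearest -2.74), and its head minus abdomen difference there was -0.443 (nearest -2.34). In abdomens of control population 1, FBtr0076196 changed by 0.116 (nearest 5.50), FBtr0077013 by 1.65 (nearest 4.29) and FBtr0070504 by -4.03 (nearest -6.15) from day 1 to day 5.

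The change from day 5 to day 50 differed between head and abdomen for 203 transcripts in a test of the difference itself. The head minus abdomen difference was 2.64 for FBtr0082621, 2.53 for FBtr0091895, -2.56 for FBtr0078265 and -2.49 for FBtr0080558. For all of these but FBtr0078265, abdominal levels near the ends of the measured range limit the comparison. Of the 32 ways of exchanging the tissues within populations, 1 gave as many transcripts, the real one with 203, and the highest of the others gave 11. A share of 1 of 32 lies under 0.05 but is the smallest these ways allow. The number of contrasts tested was not allowed for, and biological replicate 1 alone gave 6.

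The 5 heads with a day-1 score opposite to their label belonged to control populations 2 and 3 and selection population 3. Poor hybridisation or degraded RNA is argued against for 4 of the 5, which correlated with arrays of the state their score gave at 0.959 to 0.982. That was at least as well as the lowest correctly scored array, a low bar of 0.922 and 0.907 set by arrays of low correlation. The day-30 head of control population 3, replicate 1, fell just under it (0.9211), so poor quality stays open for that head. A shifted state of the flies is argued against by the abdomens of the same label, since 0 of 5 shared the shift. An exchange of the day-30 head of selection population 3 with the day-1 head of control population 3 in replicate 2 stays open: the regime score of the former exceeded that of the latter by 1.19, on the side of the labels, but the spread of such a difference was 0.793. Wrong labels of another kind may explain the heads and were not tested.

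Control population 1 lay between the states on day 1 in both tissues. A single faulty array is argued against, since 4 of 4 arrays were in between. A mixture of RNA from day-1 and older flies would give the same day-1 share in transcripts high and low on day 1. But the shares were 0.284 and 0.826 in abdomens and 0.229 and 0.55 in heads, differences of 0.542 and 0.322 in size. Standard errors of 0.0387 or less for each share came from resampling transcripts. They do not measure spread between arrays or populations. An age between the sampled days may explain these arrays and was not tested.

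In heads, 2755 transcripts separated the regimes at an unadjusted p under 0.05, where chance would give 832. Arrays of opposite score or low correlation are argued against as the whole cause, because 2550 transcripts did so without them, and uneven signal distributions are argued against by 2609 after quantile normalization, both above the limit of 1248 set in advance. With biological replicate 1 alone the number was 683, under that limit and under the number chance would give, while replicate 2 alone gave 2142; it was 1567 without control population 1, 1616 without selection population 2, 3575 with population number as a block, and 5450 with biological replicate as a further block in a fit that counted arrays as independent. Of the 10 splits of the 6 populations, 1 gave as many, the real one, and the highest of the others gave 1599, but 10 splits are too few for a share under 0.05. A broad effect of selection in heads may underlie the excess, as a hypothesis found and tested on the same data, and the 3 populations a side leave drift between populations open and untested.

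Other splits were counted for the remaining contrasts. For the regime effect in abdomens 9 of 10 splits gave as many transcripts at an unadjusted p under 0.05 as the real 225, and the highest gave 3613, with control populations 1 and 3 and selection population 3 on a side. The same split gave the highest count, 3269, for the tissue difference in the regime effect, where 6 of 10 reached the real 556. Counts several times the real ones point to some structure among the populations, which was not tested. For the regime difference in ageing, 2 of 10 splits reached the real 840 in abdomens (highest other 1444) and 9 of 10 the real 157 in heads (highest other 819). In each of these 10 splits are too few for a share under 0.05.

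For the contrasts of days, labels were exchanged within populations in 32 ways. With all arrays, only 1 of 32, the real one, reached the real count for ageing in abdomens (real 152, highest other 16) and heads (293 and 16). The same held for day 15 against day 5 in abdomens (122 and 17), maturation in abdomens (8362 and 6697) and the tissue effect (5597 and 0). A share of 1 of 32 lies under 0.05 for each contrast alone. It is the smallest share 32 ways allow, and the number of contrasts was not allowed for. For maturation in heads 2 of 32 gave as many, so this count alone cannot exclude chance at 0.05. The higher one, with 3349 transcripts against the real 3249, exchanged control population 3, whose day-1 heads scored like later days. The day-1 score, with transcripts chosen on the other population numbers, argues against chance as the cause of the whole difference. On it 8 day-1 heads lay between 0.929 and 1.4, and 45 heads of later days between -0.0886 and 0.198. Against this, 5 heads lay opposite to their label and 2 in between.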

How the results depend on the processing

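The alternatives without heads of opposite score, without arrays of low correlation as well, and without control population 1 on day 1 were chosen after seeing the data, the others before. The tissue effect and maturation in abdomens stayed within 1.5 times their counts under every alternative run, and the regime difference in ageing in heads stayed at 0. Among transcripts with a mean signal above the median, where fewer were tested, ageing gave 76 transcripts in abdomens and 88 in heads and the tissue difference in ageing 66. With biological replicate 1 alone these counts were 74, 55 and 6, and maturation in heads gave 560; with replicate 2 alone ageing gave 34 and 180. With all arrays and population as a random block, ageing gave 252 and 517 and the tissue difference in ageing 343. The regime effect in heads then gave 47 and its tissue difference 5, with arrays counted almost as independent replicates of the regime. The F test over all days gave 1 for the regime difference in ageing in abdomens. Without the heads of opposite score, ageing in heads gave 835 and its tissue difference 346; without arrays of low correlation as well these were 1353 and 536, and maturation in heads 5300. The ageing index difference in heads then reversed to -0.0526 (exact permutation p 0.8), against -0.25 in abdomens (exact permutation p 0.1). Leaving out each population gave 45 to 158 for ageing in abdomens, 103 to 237 in heads, 1612 to 4020 for maturation in heads, 109 to 225 for the tissue difference in ageing, and 0 to 1 for the regime effect in heads; for the head index difference the range was 0.05 to 0.46. The lowest of these lacked selection population 3, selection population 1, selection population 1 and selection population 2 in that order, and control population 2 for the index. Median centring changed the split of ageing in abdomens to 57 up and 94 down and of maturation in heads to 2156 up and 1411 down. Beyond the smaller numbers of transcripts or arrays in some alternatives, the cause was not tested.

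The labels speak of pairs of selection and control populations without saying that the population number marks them. Same-numbered populations deviated from their regime means with correlations of -0.0335, 0.352 and 0.436 in abdomens and 0.256, 0.0647 and 0.314 in heads. For populations of differing number the correlations ran from -0.593 to 0.336 in abdomens and from -0.35 to 0.18 in heads. The main fits left them unpaired, as planned in advance, and these correlations do not exclude pairing by number. With population number as a block, limma gave 0 transcripts for the regime effect in both tissues and for its tissue difference (385, 3575 and 1228 at an unadjusted p under 0.05). With population number and biological replicate as a block over all arrays, the regime effect gave 1 in abdomens and 2379 in heads, where the correlation within populations was estimated at -0.0137, so that arrays counted as independent. Of 663 values of the 42 named transcript changes, 613 kept direction and threshold, 50 kept the direction alone and 0 reversed. These changes were chosen as large, past the threshold and alike in every population. Leaving out a population thus could not reverse them, and the counts do not measure how stable other transcripts are. Not run were the gene list alternatives and 1 transcript per gene, and no signal over background was given to set a limit on dim transcripts.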

Other observations

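The values in this part were chosen after the data had been seen. Transcripts that changed with age were also sorted by their difference between head and abdomen on days 15 and 30, but changes with age before those days move transcripts between such groups, so the counts have no valid chance level and are not used here.

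Both heads of selection population 3 on day 50 were closer to each other than any other pair of replicates in heads, with a correlation of 0.997 and a standard deviation of their difference of 0.147 on the log2 scale, where the median pair had 0.378. The values of the pair were averaged like those of every other population and day.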
